A study of Mus musculus with 4 samples.

How the data were processed

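Total RNA from primary cultured mouse mesenchymal stromal cells (MSCs) at passage 5 was measured on 4 one-colour Agilent arrays. The cells carried retroviral short hairpin RNAs. The control hairpin was on 1 array, and 3 hairpins with different target sequences in Islr, the gene of the cell surface and secreted protein Meflin, were on 1 array each. Per the labels, RNA was purified on columns with DNase treatment, and Cy3-labelled cRNA was made with a linear amplification kit.

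Per the file headers, the authors scanned the arrays with Agilent Feature Extraction 11.5.1.1 (protocol GE1_1105_Oct12, array design 028005, genome build mm9). All 4 arrays lay on 1 slide, so a block for slide did not apply. The deposited values used here are the processed signal intensity of each feature, on a linear scale, after the software's background subtraction and detrending within an array. The deposited series table held that same signal intensity times 1 constant factor per array (2.10 for the control, 2.25, 2.08 and 2.02 for hairpins 1 to 3). How those factors were chosen is not stated.

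The 59305 features that are not controls covered 55681 probes, and features of a probe were averaged on the log2 scale. The files name probes by accession only. A gene symbol was given by matching the accession, without its version, to a RefSeq table. That named 28026 probes, which stand for 21154 genes, and left 27655 probes without a name and outside the main comparisons. Each array was scaled by subtracting the log2 of its 75th percentile. Probes were kept if the scanner software called them well above background on the control array or on all 3 hairpin arrays, which left 17843 probes and 13567 genes. Where a gene had several kept probes (3553 genes), the probe of highest mean signal stood for it.

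Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), the 3 hairpin arrays against the control array, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The hairpins are the replicates of the knockdown. The labels do not say whether the 4 cultures came from 1 MSC preparation, so n = 3 counts hairpins and not preparations or animals. The lone control array has no spread of its own, so the fit takes the spread between the hairpins for it and assumes that the control varies like them. The number of arrays limits the precision. A rule of size with no p-value was set beside this test: a gene counted if all 3 hairpins differed from the control by at least 2-fold in one direction. All 3 differences share the control array, so its noise alone moves them together. Gene lists, 34 in number with 906 entries, were tested with limma's camera at an inter-gene correlation of 0.01 and adjusted over the lists. An estimated correlation and 10000 random lists matched on signal served as alternatives. With an estimated correlation, camera also rests on the few residual degrees of freedom of the 4 arrays, so a list can hardly pass. A second test, limma's fry, was not set beforehand. It allows for correlation between genes, and its p was not adjusted over the lists.

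The gene lists, the tests and the rule for named genes were set before the data were examined. The rule took Islr and 27 other focal genes. It took the 12 genes with the largest increase and the 12 with the largest decrease by the smallest of the 3 differences, filled with genes that did not pass where fewer than 12 did. It also took up to 4 members per described list and, for each array, up to 4 genes farthest above and below the other 3 arrays. Additions were chosen after the data were seen. The same ranking of 12 and 12 was run among bright genes, whose brighter side lay at or above the array's 75th percentile. The ranking by array was also run among genes above background on all 4 arrays. Some single genes were named for their values and are said to be so. Where one side of a comparison lay below background, the fold is a bound against the lowest signal that the software called above background on that array. That level is not the limit of each probe. Acan on hairpin 1, with a signal of 24.5, was not called, while the lowest called signal there was 20.8. A fold given as at least a value can therefore be too high.

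The alternatives set beforehand were quantile normalization, median centring, normexp background correction (offset 50) with quantile normalization, the series table values, no filter, a filter requiring signal above background on all 4 arrays, the mean over a gene's probes, and each hairpin left out. An intensity trend in eBayes, a threshold of 0.10, removal of probes with outlier flags and a 1.5-fold rule were also tried. The normexp alternative used the median spot signal, because the files hold no mean spot signal. A filter requiring signal above background on at least 1 array, a 75th percentile over detected probes, and the inclusion of unnamed probes were added after the data were seen. The test was tried on simulated data with 1 array against 3: it recovered 0.4% of genes changed 2-fold, 34.0% of those changed 4-fold, 69.2% at 8-fold and 91.2% at 32-fold, with a mean of 4.4 false calls per simulation. Those arrays had no background floor and no filter. They held 250 changed genes of each size over 5 simulations, and the cell cycle list was shifted too. Many changed genes ease the adjusted threshold, so the rates hold for that setting only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.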

Results

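The data were 4 expression arrays of primary mouse MSCs, 1 with a control hairpin and 3 with hairpins against Islr, called hairpins 1, 2 and 3 here after their label numbers. Between 49.4% and 53.9% of the 59305 features were well above background on an array: 50.9% on the control array and 49.4%, 51.3% and 53.9% on hairpins 1 to 3. The 75th percentile of the signal was 442.5 on the control array and 414.7, 435.3 and 433.5 on hairpins 1 to 3, and no feature was saturated. Differences below are log2, hairpin minus control, given as the mean ± SD over the 3 hairpins (n = 3) against the single control array unless a hairpin is named.

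The first comparison asked how far each hairpin lowered its target. Islr, the gene of the immunoglobulin domain protein Meflin, had a signal of 454 on the control array. On hairpin 2 its signal was 70.5, which is 6.33-fold lower. On hairpins 1 and 3 it was not above background, with signals of 11 and 3.44, so that it was at least 20.5-fold and at least 29.6-fold lower. Relative to the control array, 15.8% of the Islr signal was left on hairpin 2, at most 4.89% on hairpin 1 and at most 3.38% on hairpin 3. These bounds and shares hold for the processed signal and the lowest called signal on the array, not for the probe's own limit. With normexp background correction (offset 50) and quantile normalization, the mean log2 difference over the 3 hairpins shrank to -2.61. With the signals of hairpins 1 and 3 taken as they stand, below background, the mean log2 difference was -4.98 ± 2.19, which is not a bound. It did not pass limma's test (adjusted p = 0.964), in which the spread between hairpins is the error.

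The main comparison asked which genes differ when Islr is depleted. Among bright genes, those at or above the array's 75th percentile on the control array (for lower genes) or on all 3 hairpin arrays (for higher genes), the stromal serine protease Fap was lower by a mean log2 of -2.31 ± 0.44 (4.95-fold), and the leucine-rich repeat gene Lrrc17 by -3.15 ± 1.48 (8.86-fold). The calcium channel gene Cacna1g (-2.14 ± 0.60), the carbonic anhydrase gene Car12 (-1.70 ± 0.31), the hexosaminidase gene Hexdc (-1.61 ± 0.24), Flrt1 (-1.70 ± 0.48) and the aggrecan-cleaving protease gene Adamts4 (-1.66 ± 0.73) were also below the control on all 3 hairpins. Angptl7 (-1.50 ± 0.32), Tcaf2 (-1.23 ± 0.10), the iron exporter gene Slc40a1 (-2.03 ± 1.03) and the homeodomain gene Hopx (-1.20 ± 0.14) completed the 12 that start with Islr. On the other side, Ptx3, a soluble pattern recognition protein gene, was higher by 2.04 ± 0.74 (4.11-fold), the ubiquitin ligase gene Rnf128 by 1.40 ± 0.30 and the integrin gene Itgb7 by 1.29 ± 0.10. None of these genes passed the adjusted threshold, and the ranking among bright genes was chosen after the data were seen.

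The other 9 of the 12 bright genes that rank highest by the smallest of the 3 differences had means between 0.89 and 1.14. They included the cell cycle transcription factor gene E2f2 (0.99 ± 0.06), the histone chaperone gene Asf1b (0.96 ± 0.20), the replication licensing inhibitor gene Gmnn (0.89 ± 0.19), Iqgap3 (0.96 ± 0.22) and the Hedgehog-binding protein gene Hhip (1.14 ± 0.28). The MSC surface marker gene Thy1 was at 1.12 ± 0.49, the desmosome gene Pkp2 at 0.96 ± 0.23, Trim47 at 1.00 ± 0.29 and Tinagl1 at 0.97 ± 0.23.

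**Figure D1:**
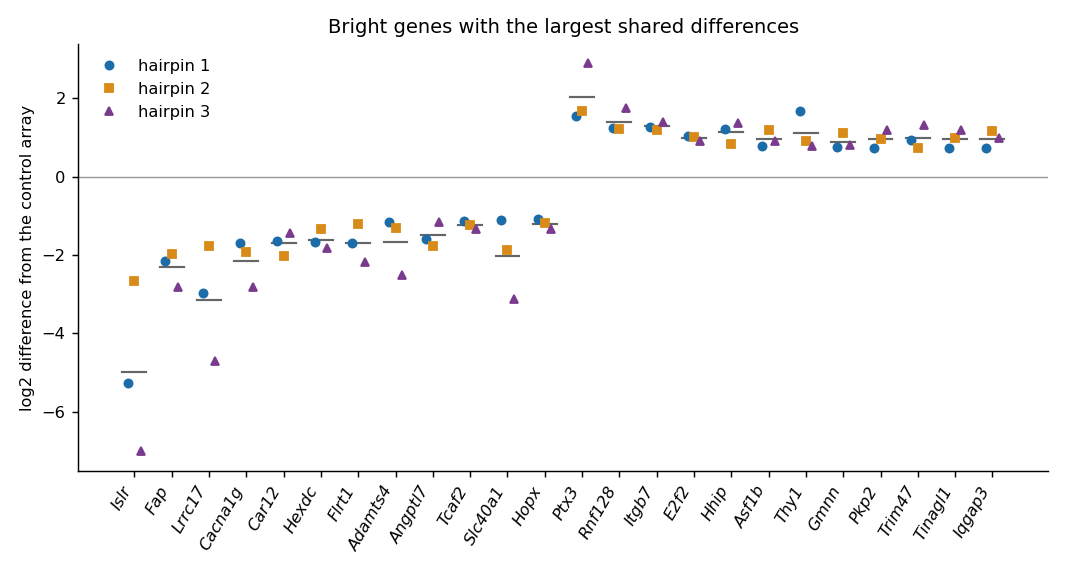
Log2 difference of each hairpin array from the control array for the 12 bright genes with the largest shared decrease and the 12 with the largest shared increase. Points are single hairpin arrays and grey bars their means. Islr was below background on hairpins 1 and 3, so its points there and its mean rest on background signal, and it has its smallest loss on hairpin 2 (-2.66). Fap lies between -1.97 and -2.80, and Ptx3 lies between 1.55 and 2.89.

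Ranked by the smallest of the 3 differences over genes of any signal, the 12 highest were all genes that did not pass. The organic anion transporter gene Slco4a1 led with 3.33 ± 0.81, from a signal of 31.5 on the control array to 516, 177 and 313 on hairpins 1 to 3. Pawr, a pro-apoptotic regulator gene, was at 1.75 ± 0.05 (limma adjusted p = 0.0754), Cyb561 at 1.59 ± 0.13, and the keratin genes Krt19 and Krt42 at 2.03 ± 0.97 and 2.04 ± 1.02. In Qrfpr, Mucl3, the glutamate transporter gene Slc1a3, Rtn4ip1, Serpinb9f and the tachykinin gene Tac1 the control array was below background. Named after its value was seen, the serine protease inhibitor gene Serpina10 was at -1.96 ± 0.14 (limma adjusted p = 0.0791).

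Over all 13567 genes, limma called 0 genes higher and 47 lower in the knockdown arrays. At an unadjusted p under 0.05 it gave 206 higher and 449 lower, where 678 are expected by chance. All 47 called genes were below background on each of the 3 hairpin arrays, with control signals from 35.2 to 253.3 (median 80.1). The spread between hairpins that served as the error for these genes is thus that of signals below background. The 12 that rank first were the cysteine-rich gene Cypt4, Khdrbs2, the steroid dehydrogenase gene Hsd3b4, the sialyltransferase gene St8sia2, Zfp641, the olfactory receptor genes Olfr1093, Olfr49 and Olfr211, the cartilage gene Snorc, Pilrb2, Slamf7 and Satl1. Against the lowest signal called above background, which is not each probe's own limit, they were at least 5.26-fold to at least 13.5-fold lower. These bounds hold for the processed signal: with normexp background correction (offset 50) and quantile normalization their differences shrank to between -1.13 and -2.03, which is 2.19-fold to 4.08-fold, and none passed (smallest adjusted p = 0.549). A filter requiring signal above background on all 4 arrays removes these 47 by its definition and left 0 calls. With a filter on at least 1 array, added later, the 45 that kept their probe did not change in their differences, but the added genes changed the fit and the adjustment (smallest adjusted p among the 47 = 0.115), and limma called 0. Leaving out any of the 3 hairpins also left 0.

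By the rule of size, 32 genes were at least 2-fold higher on all 3 hairpins and 229 at least 2-fold lower. Of the 229, 156 had no hairpin array above background and 40 were above background on all 4 arrays. Of the 32, 12 were above background on all 4 arrays. Simulated genes with no change and a shared control gave a mean of 83.4 higher and 78.8 lower over the genes as tested, and 58.0 higher and 49.0 lower over genes above background on all 4 arrays. Over the genes as tested, the 32 higher lay below the simulated mean of 83.4 and the 229 lower lay above that of 78.8. The counts of genes above background on all 4 arrays, 12 and 40, lay below both of the means there. The simulation has no background floor and no filter, and it takes the spread between hairpins as noise. It therefore cannot decide whether the counted genes changed. Leaving out hairpin 1 or hairpin 2 gave 85 and 86 genes higher in place of 32, and leaving out hairpin 2 gave 351 lower.

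The arrays as a whole were compared over the 12716 genes whose probe as tested was above background on all 4. The root mean square log2 difference from the control array was 0.38 for hairpin 1, 0.43 for hairpin 2 and 0.54 for hairpin 3. Between hairpins it was 0.46 for 1 and 2, 0.46 for 1 and 3 and 0.51 for 2 and 3. Over pairs, the control lay 0.45 from the hairpins and the hairpins lay 0.48 from each other, so the control array stood no farther from the hairpin arrays than these from one another.

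Cell cycle genes formed the list with the smallest p. Of 39 measured members, 37 were higher on all 3 hairpins and 0 were lower on all 3. Over all genes tested, 52.2% had the same sign on all 3 hairpins, and simulated unchanged genes with a shared control gave 50.1%. Counts of members with the same sign on all 3 hairpins, here and in the lists below, are to be read beside that share. The median log2 difference of the list was 0.36 on hairpin 1, 0.79 on hairpin 2 and 0.42 on hairpin 3, and 0.50 (1.42-fold) for the mean of the hairpins. The cell cycle list rose by camera (adjusted p = 2.79e-13), while no member passed limma's test by itself, over all genes or adjusted over the list alone. With an estimated correlation, which was 0.761 in this list, the adjusted p was 0.801. By fry, the cell cycle list did not reach an unadjusted p under 0.05. Members included the mitotic transcription factor gene Foxm1 (0.87 ± 0.28), the survivin gene Birc5 (0.86 ± 0.28), the cyclin gene Ccna2 (0.75 ± 0.21) and the replication helicase gene Mcm5 (0.71 ± 0.35). The proliferation marker genes Mki67 (0.56 ± 0.20) and Pcna (0.39 ± 0.08) were looked up after the data were seen.

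**Figure D2:**
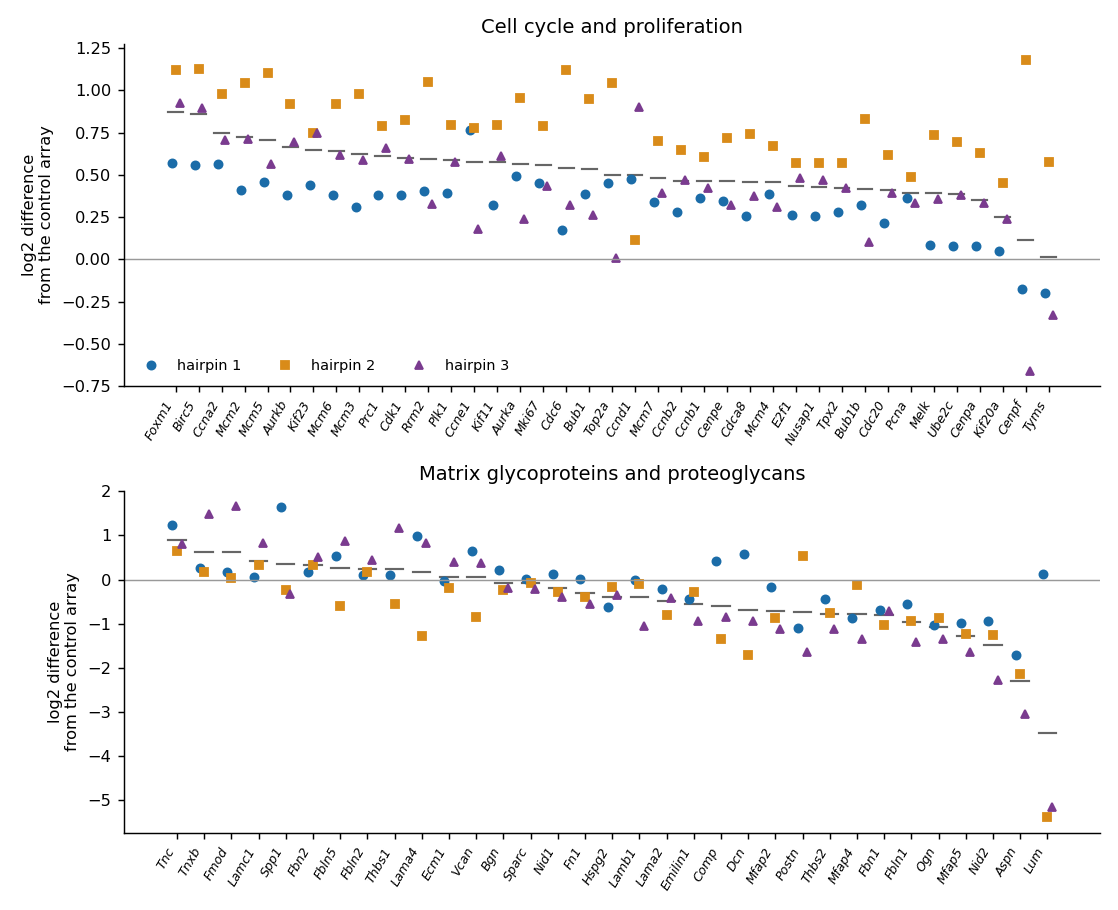
Log2 difference of each hairpin array from the control array for the measured members of the cell cycle list (39 genes) and of the matrix glycoprotein and proteoglycan list (33 genes), ordered by the mean. Points are single hairpin arrays and grey bars their means, and points below background are drawn at their signal. In the cell cycle list 37 genes lie above 0 on all 3 hairpins, and in the matrix list 13 lie below 0 and 6 above 0 on all 3.

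Hypoxia and glycolysis genes were the other list that rose by camera (adjusted p = 0.0398, and 0.801 with an estimated correlation). Of its 31 measured members, 19 were higher on all 3 hairpins and 3 lower, with medians of 0.18, 0.17 and 0.23 and a median of 0.20 for the mean. The prolyl hydroxylase gene Egln3 was at 1.01 ± 0.48, Ankrd37 at 0.66 ± 0.10 and, looked up after the data were seen, the hexokinase gene Hk2 at 0.66 ± 0.24. Car12 and Mxi1 were lower, and Mxi1 was at least 2.22-fold lower because no hairpin array was above background. That bound holds for the processed signal and the lowest called signal on each array, not for the probe's own limit. Over 11 other settings the mean difference of Mxi1 ranged from -3.46 to -0.79, and its call was kept in 2. Mxi1 was the 1 member that passed limma's test, over all genes and adjusted over the list alone. Among other settings, the call of this list ended with quantile normalization (adjusted p = 0.062) and without hairpin 1 (0.147) or hairpin 2 (0.0818).

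Matrix glycoprotein and proteoglycan genes fell by camera (adjusted p = 0.0398, and 0.801 with an estimated correlation). Of 33 measured members, 13 were lower on all 3 hairpins, 6 were higher on all 3 and 14 went both ways, and none passed limma's test, over all genes or adjusted over the list alone. The small proteoglycan genes Aspn (-2.31 ± 0.68) and Ogn (-1.09 ± 0.24), the microfibril gene Mfap5 (-1.29 ± 0.33) and the basement membrane gene Nid2 (-1.49 ± 0.70) were lower, and the tenascin gene Tnc, named after its value was seen, was higher (0.89 ± 0.30). The list median was 0.02 on hairpin 1, -0.41 on hairpin 2 and -0.42 on hairpin 3. Lum, the lumican gene, and Dcn, the decorin gene, were named after their values were seen. Lum had a signal of 187 on the control array and 190 on hairpin 1. It was below background on hairpins 2 and 3, where it was at least 9.65-fold and at least 12.2-fold lower. These bounds hold for the processed signal and the lowest called signal on the array, not for the probe's own limit. Over 11 other settings the mean difference of Lum over the hairpins used ranged from -5.27 to -1.18. Dcn was at 0.57 on hairpin 1, -1.72 on hairpin 2 and -0.93 on hairpin 3. Among other settings, the call of the list ended with quantile normalization (adjusted p = 0.062) and without hairpin 2 (0.318).

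Collagen genes and their processing enzymes did not pass as lists by camera (adjusted p = 0.288 and 0.655). Of 20 measured collagens, 8 were lower on all 3 hairpins and 1 higher. Col3a1, a fibrillar collagen gene, was at -1.35 ± 0.84, Col6a1 at -0.50 ± 0.12, Col6a2 at -0.53 ± 0.21 and Col14a1 at -0.64 ± 0.40. The type I collagen genes Col1a1 (-0.18 ± 0.20) and Col1a2 (-0.11 ± 0.13) differed by about the spread between hairpins or less. Of 21 processing enzymes, 6 were lower on all 3 hairpins, 4 higher and 11 went both ways. The lysyl hydroxylase gene Plod2 (-1.30 ± 0.58), the lysyl oxidase gene Lox (-1.13 ± 0.34) and the procollagen peptidase gene Adamts2 (-0.93 ± 0.28) were lower on all 3 hairpins, and the prolyl hydroxylase gene P4ha2 was higher (0.57 ± 0.13). No member of either list passed limma's test, over all genes or adjusted over the list alone. Of 25 matrix proteases and inhibitors, 9 were lower on all 3 hairpins and 4 higher (adjusted p = 0.304), among them Mmp19 (-0.98 ± 0.36) below and Adam12 (0.85 ± 0.10) above the control. The gelatinase gene Mmp2 was at -2.38 on hairpin 1 and -0.97 on hairpin 2, and was below background on hairpin 3.

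Contractile and lineage genes were compared because MSCs can take on myofibroblast, bone, cartilage and fat fates. The smooth muscle actin gene Acta2 was at 0.42 ± 0.32 and Tagln at 0.53 ± 0.21, both higher on 3 of 3 hairpins. Of all genes tested, 52.2% had the same sign on all 3. The enteric actin gene Actg2 was at 1.00 ± 0.24. Fap, at -2.31 ± 0.44, is in the same list and was its largest difference by the mean. Of the 19 measured myofibroblast and contractile genes, 6 were higher on all 3 hairpins, 5 lower and 8 went both ways, and the list did not pass (adjusted p = 0.655): its median was 0.14, its mean -0.001 and its camera direction up. The osteoblast regulator gene Runx2 was at 0.28 ± 0.28 and Alpl at 0.09 ± 0.32, each with hairpins on both sides of 0, and Sp7 and Bglap were below background on all 4 arrays. Sox9, the cartilage regulator gene, was at 0.80 ± 0.66. Acan was below background on hairpin 1 and at 1.13 and 0.53 on hairpins 2 and 3. Snorc, in the chondrocyte list and called lower above, was below background on all 3 hairpins from a control signal of 144. The fat cell regulator gene Pparg was at 1.35 ± 0.76 and the lipid carrier gene Fabp5 at 1.11 ± 0.51, while Adipoq was below background on all 4 arrays. As lists, osteoblast genes (3 higher and 4 lower of 20, adjusted p = 0.772), chondrocyte genes (2 higher and 4 lower of 9, 0.304) and adipocyte genes (3 higher and 2 lower of 18, 0.772, with a median of -0.04, a mean of 0.14 and direction up) did not pass. Among 26 stromal marker genes, 8 were higher and 8 lower on all 3 hairpins (adjusted p = 0.772). Islr, the target of the hairpins, is a member of that list and among the 8 lower. The platelet-derived growth factor receptor genes Pdgfra (-0.81 ± 0.61) and Pdgfrb (-0.59 ± 0.55), Ly6a (-0.33 ± 0.33) and Cxcl12 (-0.35 ± 0.48) differed by amounts near their spread, and Gli1 was at 0.89 ± 0.12.

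Among signalling targets, BMP pathway genes had list medians of 0.23, -0.06 and 0.81 on hairpins 1 to 3, with 7 of 16 members higher on all 3 and 3 lower (camera adjusted p = 0.772). Id1, a direct BMP target gene, was at 0.94 ± 0.64 and Id4 at 1.71 ± 1.15, each highest on hairpin 3 (1.62 and 3.03). Id2 (0.55 ± 0.88), Id3 (0.31 ± 0.43), Smad6 (0.20 ± 0.53) and Smad7 (0.41 ± 0.40) had means near or below their spread. Chrd, a BMP antagonist gene, was lower at -1.62 ± 0.33, and Bambi, a decoy receptor gene, was below background on all 3 hairpins. Chrd and Bambi were the 2 members that passed when adjusted over the list alone, and neither passed over all genes. Of 28 TGF-beta targets, 9 were higher on all 3 hairpins and 6 lower (adjusted p = 0.655), with Ccn2 at 0.51 ± 0.13, Skil at 0.59 ± 0.19, Pmepa1 at -0.66 ± 0.14, the receptor gene Tgfbr2 at -0.59 ± 0.13 and Tgfb1 at -0.29 ± 0.47.

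Inflammatory cytokine and chemokine genes had medians of 0.44, 0.12 and 0.35, with 12 of 27 measured members higher on all 3 hairpins and 3 lower. Il6 was at 2.47 ± 1.34, the acute phase gene Saa3 at 1.48 ± 0.62 and the chemokine gene Ccl2 at 1.04 ± 0.52. The list did not pass (camera adjusted p = 0.195). It passed with genes above background on all 4 arrays (0.00828), without hairpin 2 (0.00479) and against random lists matched on signal (0.0017). The granulocyte growth factor gene Csf3 was the 1 member that passed limma's test, over all genes and adjusted over the list alone, and it was below background on all 3 hairpins. Markers of other cell types did not pass as lists: macrophage (adjusted p = 0.443), lymphoid and granulocyte (0.300), endothelial (0.615), epithelial (0.387), skeletal muscle (0.862) and glial (0.615). The macrophage genes Cd14 (0.56 ± 0.18) and Cd68 (-0.64 ± 0.33) went opposite ways. Over all 34 lists, 2 rose and 1 fell at the preset correlation, and 0 passed with an estimated correlation. The hypoxia list lost its call there though its estimated correlation, -0.0235, lay below the preset 0.01. Such a loss cannot be laid to correlation between genes alone, because that test rests on few residual degrees of freedom. By fry, at an unadjusted p under 0.05, the hypoxia, lymphoid and epithelial lists passed. The cell cycle and matrix glycoprotein lists did not. Against random lists matched on signal, which ignore correlation between genes, 6 were higher: cell cycle and inflammatory genes (adjusted p = 0.0017 each), hypoxia (0.00272), BMP and TGF-beta targets (0.0143 each) and p53 targets (0.0303). In that test 5 were lower: matrix glycoproteins and matrix proteases (0.0017 each), stromal markers (0.0034), collagens (0.00971) and ribosomal protein genes (0.0143).

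The last comparison asked how far the 3 hairpins differ. Against the control array, 198 genes were at least 2-fold higher and 542 lower on hairpin 1, 255 and 556 on hairpin 2, and 430 and 739 on hairpin 3. Over genes above background on all 4 arrays the counts were 149 and 195, 191 and 277, and 365 and 404. With each hairpin array taken as the single one against the other 3, limma called 0 genes for hairpin 1, 0 for hairpin 2 and 0 for hairpin 3 over the genes as tested, and 0, 0 and 41 with the filter on at least 1 array. The filter for the genes as tested keeps probes above background on the control array alone, but not on 1 hairpin array alone. Probes with a gene name that were above background on 1 array alone numbered 265 on the control and 165, 291 and 724 on hairpins 1 to 3. Over the genes as tested, a hairpin array and the control array are therefore not on equal terms. The genes named next were above background on all 4 arrays, a condition added after the data were seen. Their values are that hairpin's log2 difference from the control. Hairpin 3 stood above the other arrays in Slurp1 (5.16), Plac9a (3.58), the cytokine gene Tnfsf15 (3.14) and the growth factor binding protein gene Igfbp3 (2.84), and below them in Syt13 (-3.22), the protocadherin gene Dchs1 (-2.89), Kcnh2 (-2.24) and the chemerin gene Rarres2 (-2.16). Hairpin 2 stood above in Lipe (1.94), Trim14 (1.76), the TGF-beta induced gene Tgfbi (1.44) and Mapk11 (1.42), and below in the secretogranin gene Scg2 (-3.33), Clca3a2 (-2.17), Palmd (-2.09) and the enkephalin gene Penk (-2.07). Hairpin 1 stood above in Clec1a (2.11), Sorcs1 (2.05), Zfp873 (1.76) and the osteopontin gene Spp1 (1.64), and below in Mpzl2 (-2.56), the coagulation factor gene F13a1 (-2.33), Stmn4 (-1.49) and the MSC surface enzyme gene Nt5e (-1.48).

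**Figure D3:**
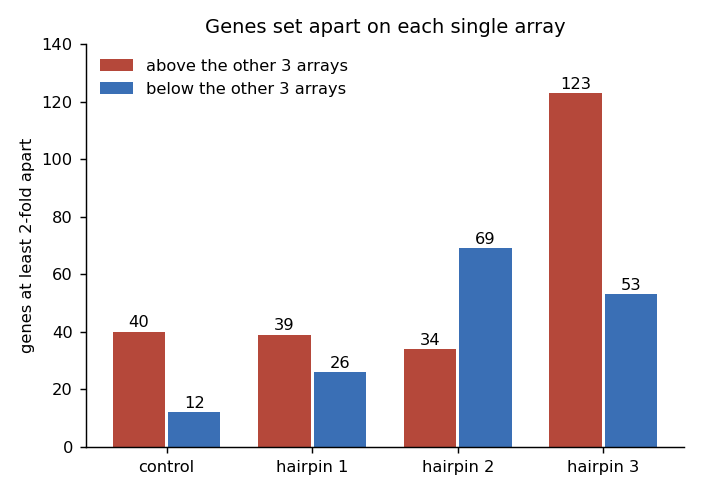
Number of genes, among 12722 with a probe above background on all 4 arrays (filtered before the brightest probe is taken, unlike the 12716 above), that lay at least 2-fold above or below all 3 other arrays, for each array taken as the single one. The control array has 40 above and 12 below, a total of 52 and the lowest of the 4, against 65 for hairpin 1, 103 for hairpin 2 and 176 for hairpin 3, of which 123 lie above and 53 below.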

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

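Calls for lower genes rested on probes that were dim on all hairpin arrays, and the lone control array has no replicate. The settings with probes above background on at least 1 array, a percentile over detected probes and unnamed probes were chosen after the data were seen. The 47 genes called lower became 75 with quantile normalization, 81 (and 2 higher) at an adjusted p under 0.10 and 138 with unnamed probes included. They became 0 with normexp, no filter, a filter on all 4 arrays or on at least 1, or an intensity trend, and 0 with any hairpin left out. Filters change which dim genes are tested. Normexp adds an offset of 50 beside control signals of 35.2 to 253.3 in the called genes, which by itself shrinks their log ratios. With a hairpin left out the fit has fewer degrees of freedom, so a loss of calls there says little about stability. For the others the cause was not tested. The 32 genes 2-fold higher on all 3 hairpins became 5 with normexp, 144 with no filter, 12 on all 4 arrays, 130 at 1.5-fold, 88 on at least 1 array and 56 with unnamed probes, and ranged from 43 to 86 with a hairpin left out. The 229 lower became 44, 40, 413 and 488 with normexp, all 4 arrays, 1.5-fold and unnamed probes, and ranged from 266 to 351 with a hairpin left out; with fewer hairpins the rule is easier to meet. By hairpin, 740, 811 and 1169 genes became 344, 468 and 769 on all 4 arrays, with fewer genes counted. The 2 lists higher became 1 with quantile normalization, median centring, the series table, no filter, at least 1 array or detected probes, 3 on all 4 arrays, 0 with an estimated correlation and 6 by random lists, and ranged from 1 to 2 with a hairpin left out. The 1 list lower became 0 in the same normalizations, with at least 1 array and with an estimated correlation, 5 by random lists, and ranged from 0 to 1 with a hairpin left out. The cell cycle median kept its call in every setting run except the estimated correlation (0.50), with 0.37 to 0.58 when a hairpin was left out. The hypoxia median lost it with quantile normalization (0.21), median centring (0.19), the series table (0.16), no filter (0.20), an estimated correlation (0.20), at least 1 array (0.20) and detected probes (0.16), and was 0.21 to 0.23 with a hairpin left out. The matrix median lost it at -0.43, -0.40 and -0.42 in the first 3 of these, at -0.38 with an estimated correlation, -0.35 on at least 1 array and -0.42 over detected probes, and was -0.48 to -0.22 with a hairpin left out. The inflammatory median gained a call on all 4 arrays (0.40) and was 0.30 to 0.43 with a hairpin left out. The cause was not tested. Islr stayed lower in the 11 settings that gave it a value, from -6.14 to -2.61 (adjusted p from 0.261 to 1); the filter on all 4 arrays removed it. There were 2189 values for 187 named entries, each a gene's mean difference or its difference on 1 named hairpin. Of these values, 2093 kept their direction and side, 89 lost a call and 3 gained one. Only genes called in the main fit can lose a call, and these mostly lost it. The 12 that rank first kept it in 5 of 11 settings each, Csf3 in 3 and Mxi1 in 2. For a gene not called there, kept means only that its sign held and no call was gained. Many such genes were picked for 1 sign on all 3 hairpins, so leaving out a hairpin cannot reverse them. For a difference on 1 hairpin, kept means a shift smaller than the SD between hairpins. Size was less stable: 95 named entries were at least 2-fold apart by the mean or on the hairpin named. Of these, 48 shrank on the log2 scale by a factor over 1.5 with normexp (median ratio 0.648), 1 with no filter and 5 of 87 without hairpin 3. Reversed were Nkd1 with no filter (0.23), Kdr as the mean over probes (0.03), Alpl without hairpin 2 and Smad6 without hairpin 3, which with a hairpin left out ranged from -0.10 to 0.20 and from -0.05 to 0.47. No paired analysis was possible because the control array has no number, and a slide block did not apply.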

Other observations

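Hedgehog genes went both ways: the pathway target genes Hhip (1.14 ± 0.28) and Gli1 (0.89 ± 0.12) were higher on all 3 hairpins, while the co-receptor genes Cdon (-1.46 ± 0.72) and Gas1 (-0.72 ± 0.13) were lower. Of 13 measured members of that list, 2 were higher and 6 lower on all 3 (camera adjusted p = 0.655). Keratin genes Krt7 (1.38 ± 0.52) and Krt19 (2.03 ± 0.97) were the 2 of 7 measured epithelial markers higher on all 3 hairpins, with 0 lower. In the insulin-like growth factor system, Igf1 was at -0.96 ± 0.69 and the receptor gene Igf2r at -0.96 ± 0.35, and Igfbp5 was below background on all 3 hairpins from a control signal of 153 (limma adjusted p = 0.0679). Among 23 Wnt genes, 7 were lower on all 3 hairpins and 2 higher (camera adjusted p = 0.304), with Wnt5b at -0.98 ± 0.32, Dkk2 at -0.85 ± 0.27 and Sfrp2 at 1.19 ± 0.93.

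Among probes with no gene name, 2 bright probes were at least 2-fold lower on all 3 hairpins and 0 were at least 2-fold higher. The probe A_55_P2025944 was at -1.24 ± 0.25, and a probe for a transcript on chromosome 17 from 12990484 to 13018375 (mm9) was at -1.83 ± 1.15.

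The tests that follow were chosen after the results were seen, except the random lists, which were set beforehand. The first pattern is the 47 genes called lower. All 47 had no hairpin array above background. With the filter on at least 1 array, the median of their differences stayed at -4.08 with a median SD of 0.28. The loss of the calls there therefore does not bear on whether the differences are real. That SD is the spread of signals below background on the hairpin arrays. It and limma's p for these genes do not measure how a detected transcript varies. With that filter and hairpin 3 taken as the single array, limma called 41 genes. A candidate explanation is that the filter keeps probes above background on the control array alone. Real loss of dim transcripts with Islr stays open as untested.

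The second pattern is the higher cell cycle list. The list median lay above those of all 10000 random lists matched on signal (percentile 100), which argues against a scaling difference between arrays. The range of the 3 hairpins' list medians was 1.19 times the smallest of them, so variation between single cultures, such as growth state at harvest, may account for the size of the difference from 1 control culture. By hairpin, the list median did not follow the loss of Islr. It was highest on hairpin 2 (0.79), with 15.8% of the Islr signal left, against 0.36 on hairpin 1 and 0.42 on hairpin 3, with less left. There is 1 array per hairpin, so this order cannot decide the question. An effect of Islr depletion stays open as untested, since the control has no replicate.

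The third pattern is the larger number of genes set apart on hairpin 3. Among genes bright on all 3 other arrays, 60 were at least 2-fold apart on hairpin 3, 37 on hairpin 2, 12 on hairpin 1 and 10 on the control. Of the 60, 39 lay above (6 on hairpin 2) and 21 below (31 on hairpin 2). With bright set by the brighter side the counts were 97 on hairpin 3 and 43 on hairpin 2, but a gene can then count through its own rise. The 39 above were bright on all 4 arrays, where the control had 7 such genes, hairpin 1 had 4 and hairpin 2 had 6. These counts argue against noise in dim probes for the genes above. For above and below together, noise in dim probes cannot be told apart from a real difference. The excess of 60 over 37 is not beyond 1.5 times by more than counting error. A deeper loss of Islr cannot be told apart from other properties of that culture: hairpin 2, with most Islr left, had 468 genes at least 2-fold from the control and hairpin 1 had 344, but there is 1 array per hairpin. Effects of the hairpin sequence on other genes stay open as untested. Taking each of the 4 arrays as the single one, the control array had 52 genes at least 2-fold apart over genes above background on all 4 arrays. This was the lowest of the 4. The other splits had 65, 103 and 176, and 4 splits are too few for a share under 0.05. The order depends on the filter. Over the genes as tested, whose filter keeps probes above background on the control array alone, the control had 261 and hairpins 1 to 3 had 133, 144 and 251. With the filter on at least 1 array the control had 315 and hairpins 1 to 3 had 315, 375 and 529.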
